A study of Mus musculus with 8 samples.

How the data were processed

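The series holds 8 one-colour Agilent arrays of mouse cDNA, 4 of resident microglia and 4 of invading macrophages, from 4 bone-marrow-chimeric animals. Per the labels' protocols, RNA was extracted with a column kit, mRNA was isolated on magnetic beads, its cDNA was amplified by a global PCR (SuperAmp, a proprietary protocol) and the product was labelled with Cy3. Amplification of this kind can change the proportions of transcripts, and does so in the same way for both groups only if their RNA input and quality were alike, which the labels do not give. Per the file headers, the arrays were read with Agilent Feature Extraction 10.7.3.1, which subtracted background and corrected trends across the array. The processed signal is an intensity that the authors deposited in each array's file, not normalized between arrays. A table of log2 values for the same arrays was also deposited by the authors, and its columns had medians of 4.604 to 4.606 and correlated with their own array at 0.996 to 1.000. Its values look quantile normalized, but the centring and the normalization are not given in the sources used here.

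Each array has 62976 spots, of which 59305 measure genes and 3671 are controls, which were left out. Spots flagged as outliers were left out, replicate spots of a probe were averaged on the log2 scale, and each array's 75th percentile was subtracted. A probe was tested if it was well above background on at least 4 of the 8 arrays, which 29323 of 55681 probes met. Probes were named through RefSeq accessions (27579 probes), current symbols (3501) or synonyms that point to 1 gene (394) of the GRCm38.p6 gene table, used for names only, and 24207 probes stayed unnamed. Coordinates are those of the array files, in build mm9. Of several probes of a gene the passing probe with the highest mean stood for it. This concerned 3978 genes, and of 284 called genes with several probes, 18 had another probe of opposite sign. Ly6c2 was not matched to a probe and is not analysed here. Some genes that the rule or the lists take are not reported here by name.

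Macrophages were compared with microglia with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over the 13214 genes. The threshold was an adjusted p of 0.05. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6. A gene not well above background on any array of a group has only a bound there. Its fold was taken between the brighter group's mean and the mean of, per array, the higher of the lowest signal among probes well above background and the gene's own signal. Where some arrays of the dimmer group measured a gene well above background, their number is given, and signals under that array floor were raised to it before the fold was taken. Fold changes otherwise are differences of mean log2 signals. Differences are macrophages minus microglia throughout.

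The groups, the tests, the alternatives, 25 lists of biological genes and 13 lists of cell type markers were fixed before the data were examined. The 33 lists with at least 5 tested members, other than the sex-linked and housekeeping lists, were tested with camera at a preset correlation of 0.01. Under an estimated correlation no list passed, and with fry, which asks whether the genes of a list move 1 way on balance and sets them against no other genes, 2 lists were higher and 2 lower. Those lower with fry were the homeostatic microglia and purinergic lists (adjusted p = 0.000108 and 0.0133). Those higher were the monocyte and natural killer cell lists (fry, adjusted p = 0.00414 and 0.0419). The type I interferon, endothelial, cell cycle, oxidative phosphorylation and Toll-like receptor lists missed the threshold with fry (adjusted p = 0.0627, 0.114, 0.204, 0.215 and 0.235). Named genes were chosen by a rule: the 6 with the largest change in each direction among called genes that moved the same way in all 4 animals, a set of landmark genes, the 2 strongest members of each biological list with the strongest called member in the other direction, the brightest member of each marker list, and Xist, Ddx3y, Actb and Gapdh. Members of a list that are named beside its count without being in this set were chosen after their values were seen, and so were the notes on other probes of a gene.

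The labels give the animal of each sample, and replicate numbers follow the animals, so that samples are paired by design. Deviations from the group means correlated within animals A, B, C and D at 0.0704, 0.114, 0.0855 and -0.00133 across genes. In A, B and C, but not in D, the microglia array correlated most in this way with the macrophage array of its own animal. These values do not show that the pairing can be ignored. The fit without the animal is the one reported, and the blocked fit stands beside it where a named gene lost its call. Genes called only with the block are named or counted only in part. Slides were also tried as a block, with and without the animal as a block, and separately. Other alternatives were normexp background correction with an offset of 50, quantile normalization, median centring, another percentile, a looser and a stricter filter on dim probes, trended and robust eBayes, array weights, the deposited log2 values, the mean of a gene's probes, all probes, a threshold of 0.01, and leaving out each array or animal. The mean of the endothelial markers as a covariate was added after seeing the data.

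The test was checked on simulated data with the 13214 genes and 2 groups of 4 arrays. It recovered 5.97% of 67 genes changed by 1 on the log2 scale, 44.8% of 67 changed by 2 and 71.2% of 66 changed by 3, with 2 calls among unchanged genes, and none with nothing changed. Of 33 lists the 1 that was shifted was called, and so was 1 other. Simulated genes varied independently of each other, each with 1 spread for all arrays. In the real lists the estimated correlation reached 0.875, for endothelial markers. The check therefore does not cover correlated genes or an outlying array. Animals, not technical repeats, are the replicates of each group. No sequence of the genome was used here.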

Results

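Gene expression was measured in resident microglia and in invading macrophages of the mouse brain 7 days after focal ischemia. The C57BL/6 mice carried transplanted bone marrow, and their brains had been ischemic for 30 min (MCAo, occlusion of the middle cerebral artery). Cells were separated by fluorescence sorting, with GFP marking the resident microglia and RFP marking the invading macrophages. Each of 4 animals, labelled A to D, gave 1 sample of either kind, so that 8 samples were hybridised to 8 one-colour arrays. RNA had been amplified by a global PCR before labelling. Between 45.7% and 57.1% of the 55681 probes were well above background on an array, and no gene probe was saturated on any array. The shares were 50.6%, 52.5%, 57.1% and 52.1% for microglia replicates 1 to 4, and 45.7%, 56.8%, 51.9% and 50.4% for macrophage replicates 1 to 4. Of 22449 named genes, 13214 were bright enough to be tested. The number of arrays limits the precision of each value.

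Arrays of 1 group resembled each other, with the exception of macrophage replicate 2, from animal B. Across genes, which are not independent replicates, the microglia arrays correlated with each other at r = 0.937 to 0.962. The macrophage arrays other than replicate 2 correlated at 0.940 to 0.960, while replicate 2 correlated with them at 0.828 to 0.867. Markers of endothelial cells, which line blood vessels, had a median of 6.24 on macrophage replicate 2 (log2, relative to the array's 75th percentile). On macrophage replicates 1, 3 and 4 their medians were 1.42, 3.07 and -0.00440, and on the microglia arrays they ran from -1.85 to -0.151. Markers of macrophages at the borders of the brain went the other way on replicate 2, with a median of 1.43 against 2.29 to 4.16 on the other macrophage arrays.

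The comparison asked how invading macrophages differ from resident microglia in the same injured brains. Of 24 genes that define microglia in the healthy brain, 19 were lower in the macrophages (14 with the animal as a block), and of 32 genes of blood monocytes, 16 were higher (11 with that block). As sets these lists had adjusted p = 0.109 and 0.288 with an estimated correlation (camera). With fry, which sets a list against no other genes, their adjusted p was 0.000108 and 0.00414. Sall1, a transcription factor of microglial identity, was at least 198-fold lower in macrophages, where 1 of 4 arrays measured it well above background, and P2ry12, a purinergic receptor of resting microglia, was 9.27-fold lower. Ccr2, the chemokine receptor by which monocytes leave the bone marrow, was 5.53-fold higher in macrophages. In all, 398 genes were higher in macrophages and 567 were higher in microglia (limma, Benjamini-Hochberg adjusted p under 0.05), and 374 and 552 of them differed at least 2-fold. Of these 965 genes, 964 differed in the same direction in all 4 animals, and 3244 genes had an unadjusted p under 0.05. For 116 of the 965 genes the dimmer group was not well above background on any array, so that only a bound on the fold could be given.

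These counts depended on single arrays and on the pairing by animal. With the animal as a block, 235 genes were higher in macrophages and 373 were higher in microglia, of which 192 and 357 were also called without the block. Without macrophage replicate 2 the counts were 1251 and 965, of which 396 and 564 were shared with the counts over all arrays. Leaving out microglia replicate 2, 3 or 4 gave 168, 196 and 180 higher genes and 324, 343 and 334 lower genes. Leaving out macrophage replicate 1, 3 or 4 gave 183, 199 and 255 higher genes. Of the 54 called genes taken by the naming rule, 23 lost the call in at least 1 of the 8 fits without 1 array. Among them, besides endothelial and haemoglobin genes, Tlr8, Mcm2 and Clec4e lost it in 7 of the 8, Pparg and Ch25h in 6, Tmem119, Il1a and Adora2b in 5, Cd86 and Ccl22 in 4, Tlr12, Runx3 and Ccl17 in 3, Vcan and Ifi44 in 2, and Fn1 and Csf1 in 1. The share of called genes that were higher in macrophages was 41.2%, against 59.3% with each array centred on its median and 28.7% with the percentile taken over probes detected on all arrays. The median difference of all genes was 0.04 on the log2 scale, 0.25 with median centring and -0.12 with the latter percentile, shifts of 0.21 and -0.16.

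The arrays lay on 2 slides. With the slide as a block, 215 genes were higher in macrophages and 420 were higher in microglia. On the larger slide, with 5 arrays, 4 and 93 genes passed, and on the smaller, with 3 arrays, 44 and 169. Homeostatic microglia genes had a median log2 difference of -2.61 with the slide as a block, -2.58 on the larger slide and -2.69 on the smaller. For the monocyte list these values were 1.76, 1.57 and 1.93, for type I interferon genes 1.04, 0.90 and 0.97, and for cell cycle genes 1.13, 1.06 and 1.09. Endothelial markers gave 3.75, 4.18 and 2.15, and natural killer cell markers 3.19, 3.05 and 2.23. Purinergic genes gave -1.31, -1.53 and -0.76, Toll-like receptor genes -0.58, -0.72 and -0.36, and genes of oxidative phosphorylation 0.42, 0.35 and 0.51. These last 3 lists missed the threshold on the smaller slide, with adjusted p = 0.0690, 0.0788 and 0.0920 (camera).

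The genes with the largest fitted reductions in macrophages were Gm10790, Sall1, Gm5796, Gm3715, Gm3264 and Gm10406. Gm10790 was at least 185-fold lower (adjusted p = 0.000202), Gm5796 258-fold, Gm3715 125-fold and Gm3264 188-fold, and Gm10406 was 245-fold lower (limma, each lower in 4 of 4 animals, as the naming rule required). Of the 4 macrophage arrays, 1 measured Gm10790 and Gm3715 well above background, 2 measured Gm5796 and Gm3264, and 3 measured Gm10406, so that these folds give no order. Gm5796 measured 4.76 ± 0.20 in microglia and -3.56 ± 0.98 in macrophages (log2, SD, n = 4). The files place the probes in mouse build mm9, at 4144179 to 4144238 on chromosome 14 for Gm5796, 4976100 to 4976159 for Gm3264, 7838959 to 7839018 for Gm10406 and 8070517 to 8070576 for Gm3715. The probe of Gm10790 lay on chromosome 13 from 42008168 to 42008227, and that of Sall1 on chromosome 8 from 91551278 to 91551337. Whether a probe lies in a coding exon or a UTR was not determined here.

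The genes with the largest fitted increases in macrophages were Ptprb, Slco1a4, Hba-a1, Erg, Itm2a and Slco1c1. Ptprb, a phosphatase of blood vessel endothelium, was at least 63.6-fold higher (adjusted p = 0.0169), and Erg, an endothelial transcription factor, at least 38.5-fold higher (adjusted p = 0.00941, limma). The transporters Slco1a4 and Slco1c1 of the blood-brain barrier were at least 72.4-fold and 54.5-fold higher, and Itm2a was at least 59.2-fold higher. These bounds rest on means over all 4 macrophage arrays and were not taken without replicate 2. On macrophage replicates 1 to 4 Slco1a4 measured 1.49, 7.19, 3.18 and -2.42, and Slco1c1 0.95, 6.81, 2.85 and -2.79 (log2). The floors of the microglia arrays were -4.23 to -3.60. Hba-a1, a haemoglobin gene, was at least 70.2-fold higher, with 1 of 4 microglia arrays well above background. All of these genes were higher in 4 of 4 animals, as the naming rule required, and endothelial markers were highest on macrophage replicate 2. Whether these transcripts come from the macrophages or from other cells in the samples was not tested. Without that array the fitted log2 differences, which are not bounds, were 6.61 for Ptprb, 6.46 for Slco1a4, 5.99 for Hba-a1, 6.00 for Erg, 5.39 for Itm2a and 5.20 for Slco1c1, in place of 8.09, 8.07, 7.43, 7.34, 6.98 and 6.81. Without macrophage replicate 4 they were 9.55, 9.66, 8.15, 7.995, 8.33 and 8.39. That of Erg was 8.04 without macrophage replicate 1, and that of Hba-a1 was 8.93 without microglia replicate 4 and 6.74 without microglia replicate 3. Erg was called whichever array was left out, but Slco1a4, Hba-a1, Itm2a and Slco1c1 lost the call in 6 of the 8 fits without 1 array, with adjusted p of up to 0.0709, 0.120, 0.104 and 0.131 (limma). For Hba-a1 the exceptions were the fits without microglia replicate 4 or macrophage replicate 2, and for the other 3 genes those without macrophage replicate 2 or 4. Ptprb lost it without microglia replicate 2, 3 or 4 (adjusted p = 0.0535, 0.0533 and 0.0516). With the animal as a block, Slco1a4 (adjusted p = 0.0521), Hba-a1 (0.106), Itm2a (0.0890) and Slco1c1 (0.103) missed the threshold. Their probes lay in mm9 on chromosome 10 from 115824180 to 115824239 for Ptprb, on chromosome 16 from 95581954 to 95582013 for Erg, and on chromosome 6 from 141754675 to 141754734 for Slco1a4 and from 141517875 to 141517934 for Slco1c1. Those of Hba-a1 and Itm2a lay on chromosome 11 from 32183955 to 32184014 and on chromosome X from 104592916 to 104592975.

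Of 24 measured homeostatic microglia genes, 19 were lower in macrophages and none was higher, and adjusted over the list alone 22 were lower. With the pairs of each animal blocked, 14 were lower. The median log2 difference was -2.77, or -2.48 with genes below background at their bound. The list passed as a set (camera, adjusted p = 4.12e-21), but with an estimated correlation the adjusted p was 0.109. Crybb1 was at least 58.5-fold lower and Sall3, a relative of Sall1, at least 2.80-fold lower. P2ry12 measured 7.17 ± 0.35 in microglia and 3.96 ± 0.50 in macrophages (log2, SD, n = 4, adjusted p = 0.000587, limma). Tmem119, a surface protein used to mark microglia, was 3.90-fold lower (adjusted p = 0.0275), but its adjusted p was 0.0577 with the animal as a block. Cx3cr1, the fractalkine receptor, had a log2 difference of -1.17 (adjusted p = 0.0646) and passed without macrophage replicate 2 (-0.87, adjusted p = 0.0245, limma). Siglech differed by -1.16 at its brightest probe (adjusted p = 0.00979, 0.0506 with the animal as a block), while its other probes gave -6.69, near the array floor in macrophages, and -6.45. The other probes of Cx3cr1 gave -2.23 and -2.24.

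**Figure D1:**
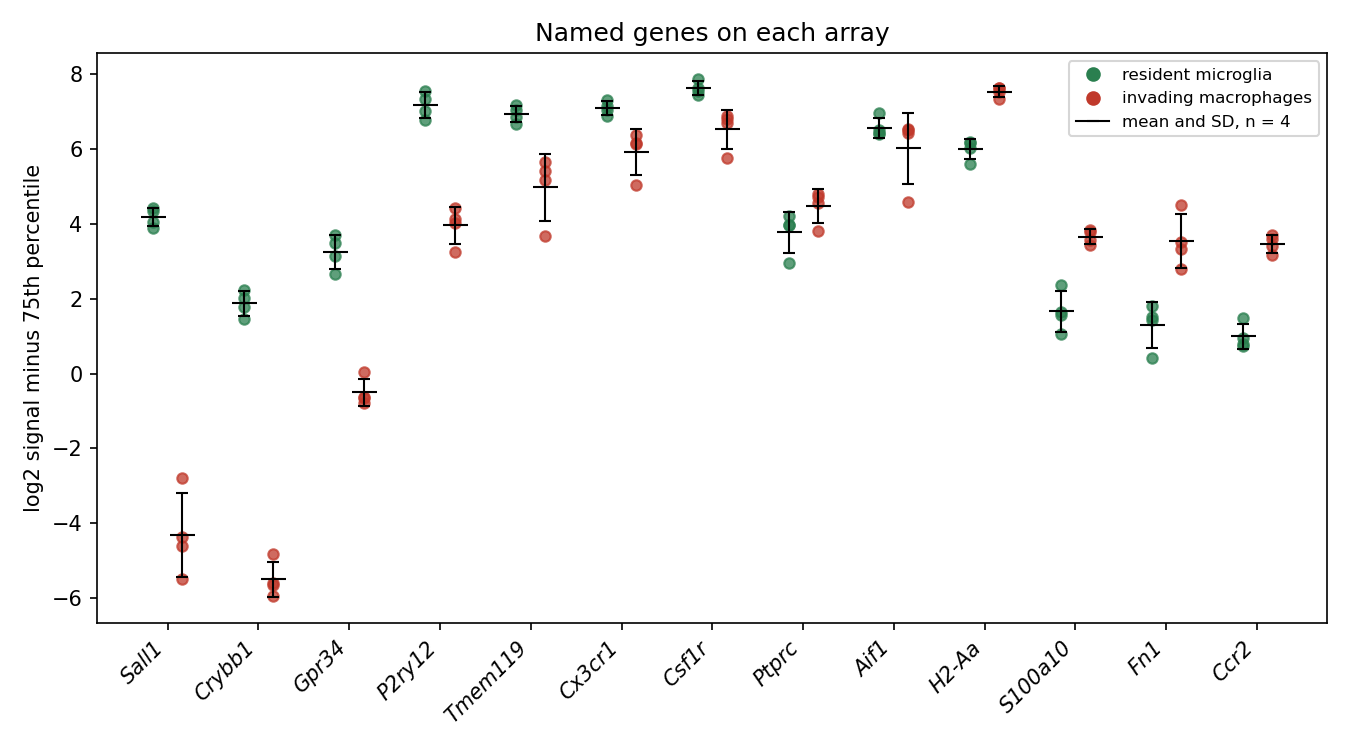
Log2 signal relative to the array's 75th percentile of named genes in resident microglia and invading macrophages, with 1 point per array and bars for the group mean and SD (n = 4). Sall1 and P2ry12 lie lower on all macrophage arrays than on any microglia array, and Ccr2 lies higher.

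Of 32 measured genes of blood monocytes and monocyte-derived macrophages, 16 were higher in the macrophages and none was lower, and adjusted over the list alone 21 were higher. With the animal as a block 11 were higher. Among them were Thbs1 and Chil3 (adjusted p = 0.0247 and 0.0280), which were not called without the block (0.203 and 0.270, limma). The median log2 difference was 1.79 (camera, adjusted p = 1.09e-11), with adjusted p = 0.288 with an estimated correlation. Ccr2 measured 0.99 ± 0.34 in microglia and 3.46 ± 0.24 in macrophages (log2, SD, n = 4, adjusted p = 0.000756, limma). S100a10, an annexin-binding protein, measured 1.66 ± 0.54 and 3.66 ± 0.19 (adjusted p = 0.00608, limma). The integrin chain Itgal was 4.83-fold higher. Fn1, which encodes fibronectin, was 4.71-fold higher (adjusted p = 0.0184), with adjusted p = 0.0856 with the animal as a block. Vcan, the proteoglycan versican, was at least 4.82-fold higher (adjusted p = 0.0206, 2 of 4 microglia arrays well above background), with adjusted p = 0.0584 with the block.

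Myeloid genes used to identify both cell types differed less. Itgam (CD11b) measured 8.88 ± 0.22 in microglia and 9.03 ± 0.34 in macrophages, Aif1 (Iba1) 6.57 ± 0.26 and 6.02 ± 0.95, and Ptprc (CD45) 3.77 ± 0.56 and 4.47 ± 0.46 (log2, SD, n = 4). None of these 3 genes passed, with adjusted p = 0.751, 0.495 and 0.262 (limma). The Itgam values are those of its brightest probe, which lay near the level of the Snap25 probe on every array (Snap25 means 8.97 and 9.01). What that Itgam probe measures was not tested, so its lack of a difference may not hold for Itgam. The other probes of Itgam were dimmer, at 5.71 and 5.88 in microglia and 4.84 and 5.15 in macrophages. They had differences of -0.87 and -0.74 against 0.15. Csf1r, the receptor of the myeloid growth factor CSF1, had a log2 difference of -1.09 (adjusted p = 0.0598), and passed without macrophage replicate 2 (-0.83, adjusted p = 0.0268, limma).

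The antigen presentation list moved in both directions. Of 15 genes, 5 were higher in macrophages and 3 were lower (5 and 5 adjusted over the list alone), and the list as a set did not pass (median log2 difference 0.01, camera adjusted p = 0.967). Leaving out macrophage replicate 2 gave 6 higher and 5 lower. The class II genes H2-Ab1, H2-Aa and H2-Eb1 were higher, the first by 2.92-fold and H2-Aa by 2.90-fold, as were Cd74, their invariant chain, and Cd40. Cd86, a costimulatory molecule, was at least 3.75-fold lower (adjusted p = 0.0225, limma, well above background on 1 of 4 macrophage arrays), and H2-Ob (adjusted p = 0.0738 with the animal as a block) and H2-DMb1 were lower. Of 14 dendritic cell genes, the chemokine gene Ccl17 was 8.07-fold higher (3 of 4 microglia arrays well above background, adjusted p = 0.0210, 0.0536 with the animal as a block) and Siglech was lower (3 and 1 adjusted over the list alone). Flt3, well above background on 1 of 4 microglia arrays, differed by 3.05 on the log2 scale without passing (adjusted p = 0.0777) and passed without microglia replicate 3 (3.85, adjusted p = 0.0266, limma). The fitted difference of Cd86 was -4.02 without macrophage replicate 4, in place of -3.34. The dendritic cell list did not pass as a set (adjusted p = 0.171), and with the animal as a block 0 and 0 of its genes were called (3 and 1 without macrophage replicate 2, median 0.34 in place of 0.63).

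Genes named for M1-type and M2-type activation did not separate the groups as sets. Of 16 M1-type genes, only Il1a (interleukin 1 alpha) was called, at least 11.4-fold lower in macrophages (3 of 4 arrays well above background, adjusted p = 0.0322, 0.0535 with the animal as a block), and adjusted over the list alone 1 gene was higher and 3 were lower (limma). Nos2, the inducible nitric oxide synthase, measured -2.69 ± 0.46 and -2.53 ± 0.49 (log2, SD, n = 4, adjusted p = 0.800, limma). Cd38 and Ptgs2 differed by 2.08 and 0.72 without passing (adjusted p = 0.0532 and 0.220, limma), and Cd38 passed without macrophage replicate 2 (2.51, adjusted p = 0.00930). The fitted log2 differences of Il1a and Cd163 were -2.96 and -4.12 without that array, in place of -3.85 and -4.75. Of 20 M2-type genes, Ccl17, Ccl22 and Pparg were higher in macrophages, while Cd163 and Ccl24 were lower (3 and 2 adjusted over the list alone). The adjusted p of Ccl24 was 0.0754 with the animal as a block. In that fit 3 M2-type genes were higher and 1 was lower. Chil3 was among those higher (adjusted p = 0.0280, against 0.270 without the block, limma). Ccl22 was at least 3.76-fold higher, Pparg, a nuclear receptor of lipid metabolism, was at least 4.23-fold higher (3 of 4 microglia arrays well above background), and the scavenger receptor Cd163 was at least 18.2-fold lower (adjusted p = 0.00496, limma, 2 of 4 macrophage arrays). Arg1, encoding arginase 1, differed by 1.88 (adjusted p = 0.430, limma), by 3.12 without macrophage replicate 2 (adjusted p = 0.0648) and by 1.14, 1.26 and 1.18 without microglia replicate 2 or macrophage replicates 3 or 4. The sets had adjusted p = 0.790 and 0.443 (camera), with medians of 0.03 for M1-type genes, whose mean was -0.16, and 0.69 for M2-type genes. Without macrophage replicate 2 the medians were 0.10 and 0.41, with 1 M1-type gene higher and 1 lower, and 5 M2-type genes higher and 2 lower.

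Among chemokine genes, 2 of 20 were higher in macrophages and 4 were lower (2 and 6 adjusted over the list alone, camera adjusted p = 0.338). Those lower were Cxcl13, the B cell attractant, by at least 16.1-fold, Ccl24, Ccl12 and Ccl3. Those higher were Ccl17 and Ccl22. Blocking on the animal left 1 higher and 1 lower, and Ccl24, Ccl12 and Ccl3 had adjusted p = 0.0754, 0.0544 and 0.0538. Of 22 chemokine receptors and integrins, 5 were higher, namely Ccr2, Itgal, Itga4, Ccr1 and Cxcr3, and Itgb3, an integrin beta chain, was lower (log2 difference -4.81; 9 and 2 adjusted over the list alone). Blocking on the animal left 2 higher, and Itga4, Ccr1 and Cxcr3 had adjusted p = 0.0872, 0.0802 and 0.0885. That list missed the threshold as a set (median 0.60, adjusted p = 0.0745) and passed without macrophage replicate 2 (0.66, adjusted p = 0.0316, 8 genes higher and 2 lower) (camera), without microglia replicate 2 (0.61, adjusted p = 0.0485) and with the slide as a block (0.51, adjusted p = 0.0410). With an estimated correlation its adjusted p was 0.759 over all arrays and 0.330 without macrophage replicate 2.

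The purinergic list holds mostly genes whose products sense or process extracellular nucleotides or adenosine. Of its 15 measured genes, 6 were lower in macrophages and 1 was higher (8 and 3 adjusted over the list alone). Their median log2 difference was -1.33 (camera, adjusted p = 0.00641, and adjusted p = 0.600 with an estimated correlation). Gpr34 was 13.5-fold lower (adjusted p = 0.000205, limma), and P2ry13, P2ry12, Adora3, P2rx1 and Entpd1 were also lower, the last 2 with adjusted p = 0.0506 and 0.0833 with the animal as a block. P2ry12, P2ry13 and Gpr34 are also in the homeostatic list. Adora2b, an adenosine receptor, was at least 6.70-fold higher (2 of 4 microglia arrays well above background). Without macrophage replicate 2 the median was -0.84, and with the endothelial marker mean as a covariate, chosen after the data were seen, it was -0.15 and the list missed the threshold (adjusted p = 0.0865, camera). With the block on the animal 4 were lower. Toll-like receptor and inflammasome genes had a median of -0.77 (camera, adjusted p = 0.00731), with adjusted p = 0.759 with an estimated correlation and 0.0831 without macrophage replicate 2 (median -0.41, 4 genes lower and 2 higher). With the endothelial covariate its median was 0.37. Of 23, Tlr12 was at least 15.4-fold lower (2 of 4 macrophage arrays well above background) and Tlr3 2.85-fold lower, while Tlr8 was 3.99-fold higher (adjusted p = 0.0450, 0.0774 with the animal as a block, limma), and adjusted over the list alone 7 were lower and 2 were higher. With the animal as a block 1 gene other than Tlr8 was higher and 2 were lower. With both the animal and the slide as blocks the list missed the threshold (median -0.29, adjusted p = 0.127, camera). The fitted difference of Tlr12 was -4.16 without macrophage replicate 3 and -5.71 without replicate 4, in place of -4.81.

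Of 25 type I interferon genes, 5 were higher in macrophages and none was lower, and adjusted over the list alone 13 were higher. Their median log2 difference was 0.98 (camera, adjusted p = 1.40e-06, and adjusted p = 0.600 with an estimated correlation). Cmpk2 was 3.91-fold higher (adjusted p = 0.00756, limma), and Ifi44 4.29-fold higher (adjusted p = 0.0203, 0.0710 with the animal as a block). Irf7 and Xaf1 were also higher, and with the animal as a block 3 of the 25 genes were called, with adjusted p = 0.109 for Xaf1. Cell cycle genes had a median of 1.05 (camera, adjusted p = 2.94e-05, and adjusted p = 0.759 with an estimated correlation), with 24 of 25 above 0. Only Mcm2, a subunit of the replicative helicase, passed by itself, also adjusted over the list alone (2.41-fold higher, adjusted p = 0.0269, 0.0747 with the animal as a block), and Ccna2 differed by 1.22 (adjusted p = 0.0631, and 0.0107 without macrophage replicate 2, limma). With the animal as a block 1 cell cycle gene other than Mcm2 was called higher. Without macrophage replicate 2, 17 of the 25 cell cycle genes and 10 of the 25 interferon genes were called higher.

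Genes of oxidative phosphorylation had a median of 0.40 with 23 of 27 above 0 (camera, adjusted p = 0.0150, and adjusted p = 0.759 with an estimated correlation), and none passed by itself, whether adjusted over all genes or adjusted over the list alone. Atp5j and Atp5b differed by 1.34 and 0.84 (adjusted p = 0.0517 and 0.0940, limma), and Atp5b passed without macrophage replicate 2 (adjusted p = 0.0350). The list missed the threshold after quantile normalization, with a median of 0.18 (adjusted p = 0.0781). The 14 housekeeping genes, which were not tested as a set, had a median of 0.46, with 13 of 14 above 0 and none called. Actb measured 7.51 ± 0.27 and 7.80 ± 0.57, and Gapdh 7.03 ± 0.27 and 7.37 ± 0.60 (log2, SD, n = 4). Of 22 glycolysis genes, Pfkp was 6.11-fold higher (adjusted p = 0.00303), although its other probe differed by 0.21, and the lactate dehydrogenase gene Ldhb was lower (log2 difference -3.70, adjusted p = 0.00176, limma). Ldha differed by 0.75 (adjusted p = 0.157), and the glycolysis list did not pass (adjusted p = 0.315), with 1 gene higher and 1 lower adjusted over the list alone and 4 and 1 without macrophage replicate 2. Without that array, 3 genes of oxidative phosphorylation and 1 housekeeping gene were called higher.

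**Figure D2:**
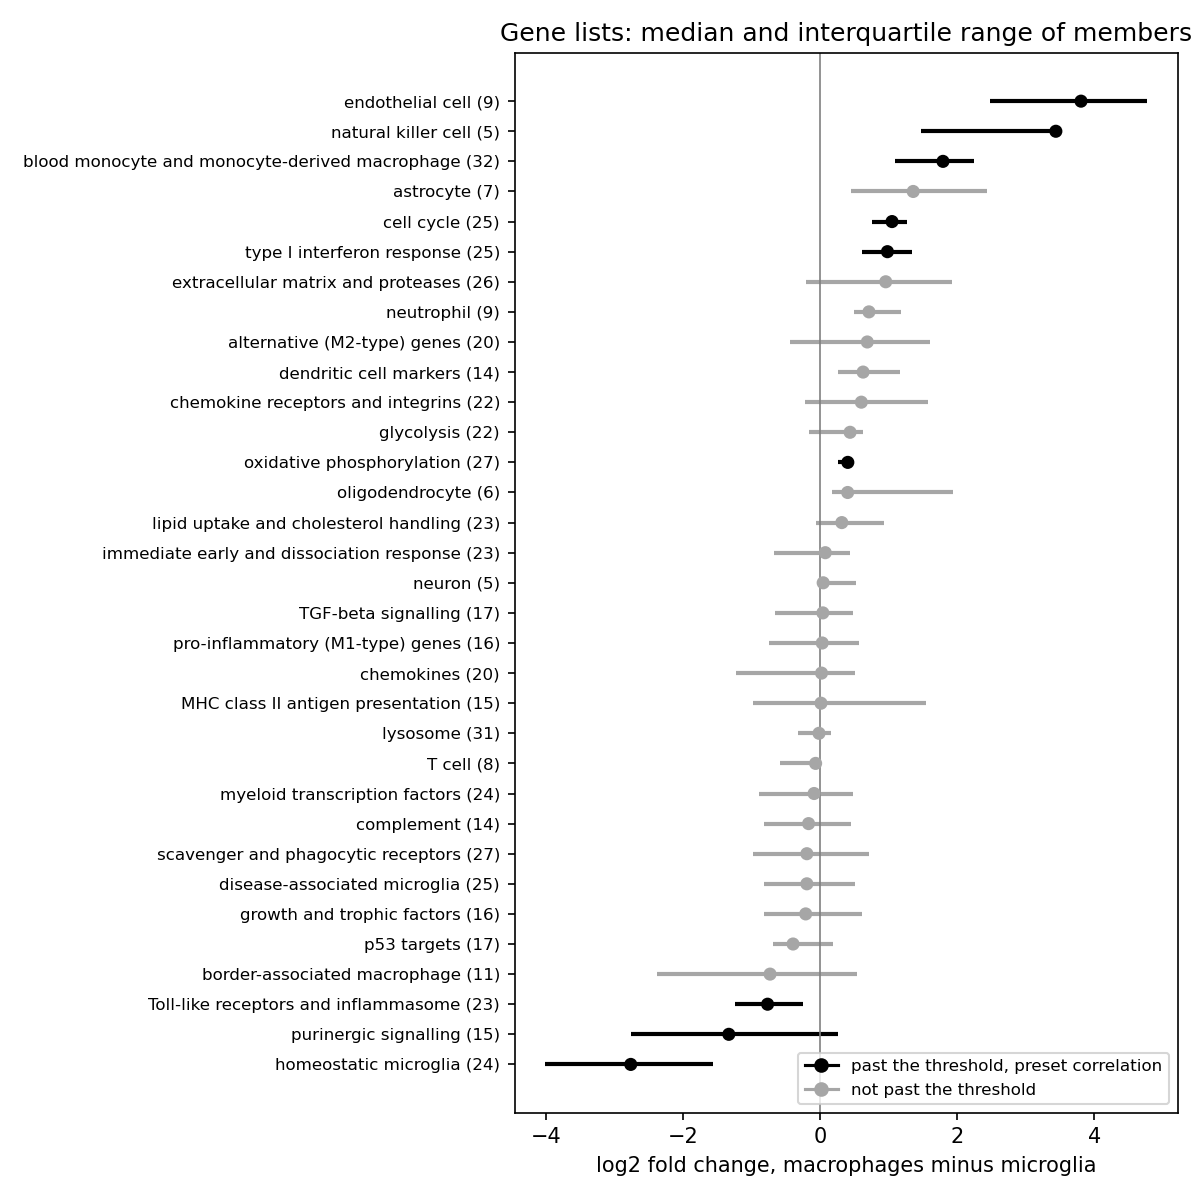
Log2 difference of macrophages minus microglia for each of the 33 tested gene lists, with a point at the median of its members, a line over their interquartile range and the number of members in brackets. Black marks the 9 lists past the threshold with a preset correlation, from the homeostatic microglia list at -2.77 to the endothelial list at 3.81; with an estimated correlation none passes.

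Disease-associated microglia genes, which microglia express around damage, did not separate the groups as a set, with 2 of 25 called, both lower in macrophages (the same number adjusted over the list alone). Without macrophage replicate 2, 4 were higher and 2 lower, with a median of 0.23. Cst7, which encodes cystatin F, was 36.0-fold lower (adjusted p = 0.00288, 22.9-fold without that array), and the growth factor Csf1 was 2.91-fold lower (adjusted p = 0.0148, limma). Their list did not pass as a set (median -0.20, adjusted p = 0.338). None of 31 lysosome genes was called by limma, also adjusted over the list alone (median -0.02, adjusted p = 0.563), but without macrophage replicate 2 the median was 0.46 and 3 genes were higher. Ctsl, a cathepsin, differed by -0.87 (adjusted p = 0.326, limma). Of 23 lipid handling genes, Pparg was higher and Ch25h, which makes 25-hydroxycholesterol, was 3.14-fold lower (adjusted p = 0.0330, 0.107 with the animal as a block), with 1 and 1 adjusted over the list alone and 2 higher and 0 lower with the block. This list did not pass (median 0.31, adjusted p = 0.342) but did so without macrophage replicate 2 (0.74, adjusted p = 0.0167, camera, 7 genes higher and 1 lower), where the adjusted p was 0.716 with an estimated correlation.

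Of 27 scavenger and phagocytic receptors, Cd163, Marco, Cd33 and Mertk were lower and Clec4e was higher (4 and 2 adjusted over the list alone, camera adjusted p = 0.338). Leaving out macrophage replicate 2 gave 5 higher and 4 lower. Mertk had adjusted p = 0.0875 with the animal as a block, where 3 genes were lower and 1 gene other than Clec4e was higher. Marco was at least 5.39-fold lower, and Clec4e was 4.33-fold higher (adjusted p = 0.0450, 0.0580 with the animal as a block, limma). Of 14 complement genes, 1 was lower and none was higher (the same number adjusted over the list alone, camera adjusted p = 0.520; 1 higher and 1 lower with the animal as a block or without macrophage replicate 2), and C4b differed by -1.24 (adjusted p = 0.161). Of 16 growth factor genes only Csf1 was called (1 adjusted over the list alone, camera adjusted p = 0.586), and without macrophage replicate 2, 1 was higher and 3 were lower. Igf1, insulin-like growth factor 1, differed by -0.41 and Gas6 by -0.71 (adjusted p = 0.769 and 0.149, limma), and Igf1 by 0.36 without macrophage replicate 2.

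Extracellular matrix and protease genes went both ways, with Fn1 and Vcan higher and Sparc and Mmp2 lower among 26 genes (4 and 2 adjusted over the list alone). Fn1, Vcan and Sparc had adjusted p = 0.0856, 0.0584 and 0.0637 with the animal as a block. In that fit 2 other genes were higher and 1 gene was lower. Thbs1 was among those higher (adjusted p = 0.0247, against 0.203 without the block, limma). Mmp2, a gelatinase, was 7.31-fold lower (adjusted p = 0.00766, limma). The list had a median of 0.96 (adjusted p = 0.0817) and passed with the animal as a block (adjusted p = 0.0144) and with the slide as a block (1.05, adjusted p = 0.0409, camera). It also passed without microglia replicate 1 or 3 (1.07 and 1.01, adjusted p = 0.0438 and 0.0386), but with an estimated correlation its adjusted p was 0.759 over all arrays and 0.716 without macrophage replicate 2. Its median was 1.34 without macrophage replicate 2, with 10 genes higher and 3 lower. Its median on macrophage replicate 2 was 1.73, against -0.17 to 0.26 on the other macrophage arrays, where endothelial markers were also lower. Of 17 TGF-beta pathway genes, Bmpr1a, a receptor for bone morphogenetic proteins, was at least 5.96-fold lower (1 of 4 macrophage arrays well above background) and Tgfbr2 was also lower, the latter with adjusted p = 0.114 with the animal as a block (3 adjusted over the list alone, camera adjusted p = 0.443). Tgfbr3 and Tgfb2 differed by 2.48 and 3.87 (adjusted p = 0.200 and 0.256, limma), with 2 and 1 of 4 microglia arrays and 4 and 3 of 4 macrophage arrays well above background. They differed by 1.28 and 2.27 without macrophage replicate 2 and by 3.17 and 5.63 without macrophage replicate 4, and Tgfb2 by 4.81 without microglia replicate 3. The fitted difference of Bmpr1a was -4.52 without macrophage replicate 4, in place of -3.89. The median of this list was 2.34 on macrophage replicate 2 and 0.57 to 0.66 on the other macrophage arrays.

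Of 24 myeloid transcription factors, Sall1, Sall3 and Etv1 (adjusted p = 0.0535 with the animal as a block) were lower and Runx3 was 5.05-fold higher in macrophages (5 and 3 adjusted over the list alone, camera adjusted p = 0.323; 4 and 2 without macrophage replicate 2). Cdkn1a, the cell cycle inhibitor p21, was the only 1 of 17 p53 targets called, also adjusted over the list alone, and was 3.19-fold lower (adjusted p = 0.00496), while Btg2 differed by -0.94 (adjusted p = 0.0746, and 0.0288 without macrophage replicate 2, limma). The p53 list had adjusted p = 0.171 (camera), and 2 of its genes were lower without macrophage replicate 2. Of 23 immediate early and dissociation genes, only Egr1, a transcription factor induced within minutes of a stimulus, was called, 4.19-fold lower (1 higher and 3 lower adjusted over the list alone and also without macrophage replicate 2, camera adjusted p = 0.443). Nr4a1 and Fosl2 differed by 1.08 and 0.58 (adjusted p = 0.0527 and 0.296, limma), and Nr4a1 passed without macrophage replicate 2 (adjusted p = 0.0317).

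Markers of other cell types were also measured. Endothelial markers had a median log2 difference of 3.81 (camera, adjusted p = 9.09e-05, and adjusted p = 0.759 with an estimated correlation), with 4 of 9 genes higher and none lower, and 7 higher adjusted over the list alone. These were Slco1a4, Cldn5, Abcb1a and Flt1. With the animal as a block none of the 9 was called, with adjusted p = 0.0521, 0.110, 0.0802 and 0.0683 for these 4, and without macrophage replicate 2 the median was 2.95 with 5 called. Pecam1 differed by 1.86 (adjusted p = 0.263, limma), and by 0.84 without that array. Natural killer cell markers had a median of 3.44 (camera, adjusted p = 7.38e-04, and adjusted p = 0.600 with an estimated correlation), with Gzmb, Ncr1 and Klrd1 among 5 genes higher and 4 higher adjusted over the list alone. Their median on macrophage replicate 2 was 1.98, against -1.12 to 0.04 on the other macrophage arrays. Without that array the list still passed (median 2.71, 3 genes higher, camera adjusted p = 0.00842, and adjusted p = 0.330 with an estimated correlation). With the endothelial covariate, which was chosen after the data were seen and correlates with the group at 0.785, the median was 0.69 and the call was lost (adjusted p = 0.470, camera). Prf1 (perforin) differed by 0.49 (adjusted p = 0.571, limma), and by -0.01 without macrophage replicate 2.

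Border-associated macrophage markers had a median of -0.73, with Cd209f and Cd163 lower among 11 genes (3 adjusted over the list alone, camera adjusted p = 0.171), and without macrophage replicate 2 the median was 0.11, with 3 higher and 2 lower. F13a1 differed by 0.76 (adjusted p = 0.357, limma) and passed without that array (1.22, adjusted p = 0.0236). None of 9 neutrophil or 8 T cell markers was called by limma, also adjusted over the list alone, and the lists had adjusted p = 0.246 and 0.408 (camera). The neutrophil list passed without macrophage replicate 1 (median 1.41 in place of 0.71, adjusted p = 0.0231), with adjusted p = 0.759 over all arrays with an estimated correlation, and 1 neutrophil gene was higher with the animal as a block and without macrophage replicate 2 (median 0.17). Csf3r and Cd6 differed by -0.32 and -0.07. Of 5 neuron markers Map2 was higher (adjusted p = 0.0506 with the animal as a block, 1 adjusted over the list alone), while Snap25 measured 8.97 ± 0.27 and 9.01 ± 0.32. That level lay above those of Actb (7.51 and 7.80), while the median of the neuron list was -2.57 to -1.08 over the arrays. Whether this probe measures Snap25 alone was not tested. Of 7 astrocyte markers Gfap was higher and Slc1a3, a glutamate transporter, was at least 94.2-fold lower (2 of 4 macrophage arrays well above background, 2 and 1 adjusted over the list alone), and of 6 oligodendrocyte markers 1 was higher (1 adjusted over the list alone), while Mbp differed by 0.44. Those 3 lists had adjusted p = 0.521, 0.369 and 0.323 (camera). Fewer than 5 members were tested for the B cell, pericyte and smooth muscle, and erythroid lists. Cd79b differed by -1.03 and Anpep by 1.98, and Anpep passed without macrophage replicate 2 (2.69, adjusted p = 0.00185, limma). Of the 2 erythroid genes tested, Hba-a1 was higher and Epor lower, each also adjusted over the list alone, and with the animal as a block they had adjusted p = 0.106 and 0.0626.

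**Figure D3:**
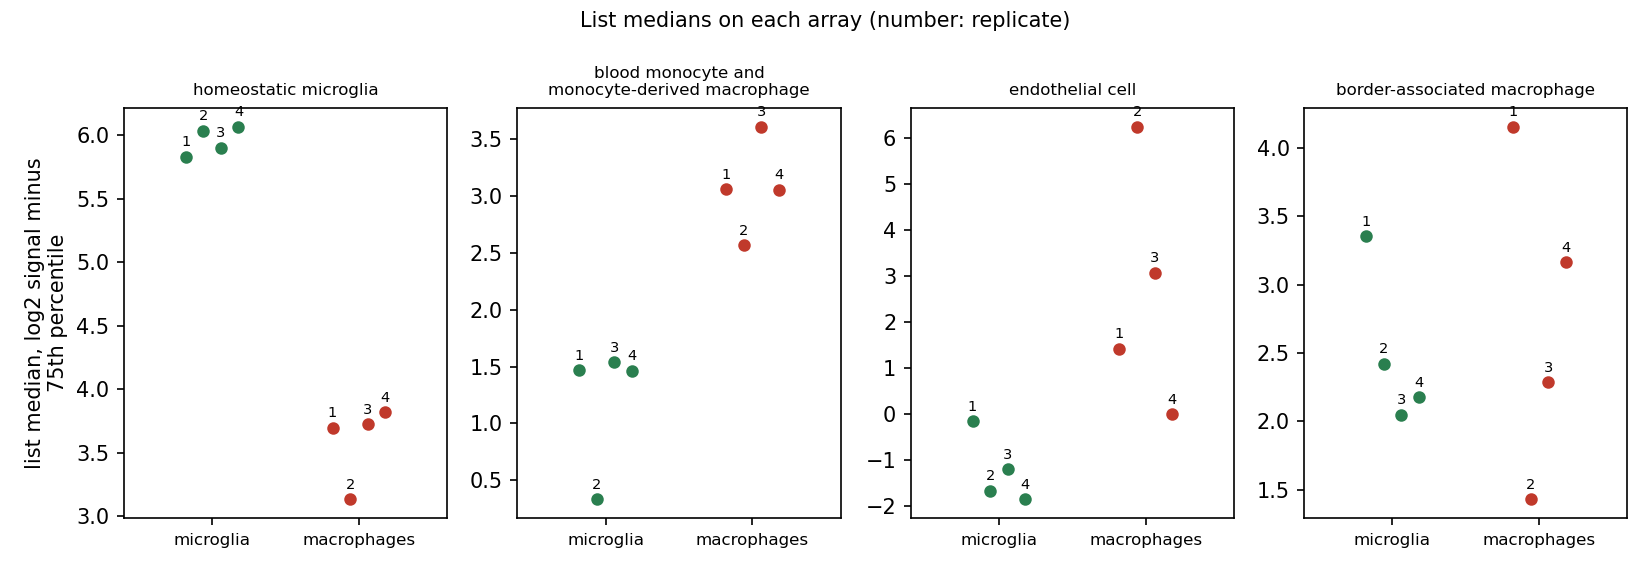
Median log2 signal, relative to the array's 75th percentile, of the homeostatic microglia, monocyte, endothelial and border-associated macrophage lists, with 1 numbered point per array and an axis of its own in each panel. The endothelial median is 6.24 on macrophage replicate 2 and at most 3.07 on the other arrays.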

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

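Of the tests below, that of compression and that of probe identity over the whole cluster were set out before their results were seen, while all others were chosen afterwards, and the chance of finding no gene in the compression test was added after that count was seen. In 186 groups of 4 arrays, 9 had a value far from the other 3, against 9.3 by chance alone, and 4 of the 9 were on macrophage replicate 2.

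On macrophage replicate 2 those values were Gm10406 at -1.38 (others -3.02 to -2.95), Aif1 at 4.59 (6.44 to 6.55), Csf1r at 5.76 (6.69 to 6.87) and Mmp2 at -2.12 (-0.32 to -0.06), in log2 relative to the 75th percentile. On microglia replicate 1, Gm5796 stood at 5.06 (others 4.64 to 4.68), Nos2 at -3.37 (-2.55 to -2.41) and Igf1 at 2.08 (1.03 to 1.19). Tgfb2 stood at -1.39 on microglia replicate 3 (-5.50 to -4.81), and Fosl2 at 0.25 on microglia replicate 2 (1.35 to 1.49). Among 11095 tested probes with no gene name, which entered no comparison above, 661 passed the threshold (limma), 193 higher and 468 lower in macrophages.

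Macrophage replicate 2 differed from the other macrophage arrays across many genes. A weak array is argued against, since 56.8% of its probes were well above background, the highest share of the macrophage arrays, and so is an exchange with a microglia sample, since its homeostatic microglia genes lay at a median of -3.08 from the microglia mean. Endothelial cells or their RNA in that sample are a candidate source: the 9 endothelial markers lay above their mean on the other macrophage arrays by a median of 4.50, and on this array each exceeded all other macrophage arrays. Sorting on RFP is meant to leave out host endothelium, but the labels give no sort purity. The border-associated and housekeeping lists moved the other way (-2.37 and -0.71), as a lower share of macrophage RNA may also give. Endothelial medians were 1.42, 3.07 and -0.00440 on macrophage replicates 1, 3 and 4, above the -1.85 to -0.151 of the microglia arrays. Such RNA may therefore not be confined to replicate 2. Neutrophil and natural killer markers also lay higher there (2.13 and 1.99), so that endothelium by itself may not account for the array, and a difference in animal B stays untested.

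The 19 homeostatic microglia genes that were lower in macrophages were so by very different factors, with a macrophage level of at most 0.506% of microglia for Sall1, 10.8% for P2ry12 and 25.6% for Tmem119. Carry-over of microglia into the macrophage gate as the whole cause is argued against only where signals follow the amounts of RNA. In that case the level of each gene caps the share that was carried over. The highest of the 5 lowest levels was 6.08%, with signals under the array floor raised to it, against a median level of 14.9% over the 24 genes. In animals A to D these values were 3.39%, 5.10%, 5.60% and 2.04% against 15.8%, 11.9%, 20.6% and 21.1%. The 5 lowest levels were picked anew in each animal and lie under the median by construction. The lowest level, that of Sall1 at no more than 0.506%, allows a smaller share still. Compression of bright signals by amplification or scanning cannot be told apart from unequal expression: of 185 genes as bright in microglia as P2ry12, 0 were lower by 4 or more on the log2 scale, where 1.85 would be expected, and none would be found with a probability of 0.153. Probes of the same gene bear on it too, since the brightest probe of Siglech differed by -1.16 and the dimmer ones by -6.69 and -6.45, which compression or other transcripts binding the bright probe may give. The probe at -6.69 had a macrophage mean of -4.03, near the floors of those arrays (-5.00 to -3.42), so the size of its difference is uncertain. The probe at -6.45 had a macrophage mean of -1.22. Expression of these genes by the macrophages themselves stays open.

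A cluster of 11 tested genes on chromosome 14 (mm9, 4144179 to 8070576) was lower in macrophages, with a median log2 difference of -6.37 when signals under the array floor were raised to it, and was picked out after its values were seen; 1 of the 11 was well above background on all macrophage arrays. Near-identical probes as the cause of the change of the whole cluster called for a median best identity of 80% between its probes. That median was 65%, with an upper quartile of 76.7%, against 40% among other genes called lower in macrophages. Matches were counted over the whole probe length, so probes of the same sequence that start at different positions score lower. The test therefore cannot decide on this cause. For 2 of the 11, Gm3696 and 4930555G01Rik, the best identity was 91.7%, and whether their probes measure the same transcripts stays open. Transcripts of the cluster may also be similar outside the probes, which was not tested without a genome. A difference in genotype between donor and host mice at the cluster cannot be told apart from a difference between the cell types, because every invading cell comes from the donor, and all 11 genes were lower in all 4 animals under either.

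The difference between the groups was set against the other ways to part the 8 arrays into 4 and 4. Of 35 splits, 1, the real one, gave as many as 965 genes, and the highest of the others gave 1. For genes at least 2-fold apart these numbers were 926 and 1, with 1 of the 35 splits as large. The real split thus stood apart, but chance is not excluded by it. Most of these splits ignore the pairing by animal, and a split that mixes the groups counts their difference as spread, which lowers its number of genes. For the number of gene lists past the threshold with a preset correlation the real split did not stand apart, and chance cannot be excluded. It gave 9, 16 of the 35 splits gave as many, and the highest other gave 15. Of these splits 8 part every animal's pair as the design does, which are too few for a share under 0.05; the real one gave 965 genes, and the others at most 0 genes and 12 lists.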

How the results depend on the processing

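The covariate of endothelial markers was chosen after the data were seen, and the other settings before. All settings of the plan were run. Counts are given as genes higher in macrophages and higher in microglia, against 398 and 567 (at least 2-fold 374 and 552). Fewer arrays or residual degrees of freedom, a stricter threshold and more or fewer probes account for part of the changes by construction. The cause of the others was not tested. With the animal as a block they were 235 and 373, and with the slide as a block 215 and 420. With both blocks they were 335 and 443. In that fit the Toll-like receptor list missed the threshold (adjusted p = 0.127, camera). The lipid handling, chemokine receptor and extracellular matrix lists passed it there (adjusted p = 0.00130, 0.0242 and 0.0147, camera). The larger slide gave 4 and 93, the smaller 44 and 169, all of them at least 2-fold. Array weights gave 1578 and 1158 (1030 and 951), with a weight of 0.197 for macrophage replicate 2. Median centring gave 685 higher (650), and the percentile over detected probes 853 lower. Without a filter 238 were higher, and with the stricter filter 343 were lower (316). A threshold of 0.01 left 82 and 265, and all probes gave 687 and 1205 (664 and 1183). The covariate, which correlates with the group at 0.785, gave 585 higher at least 2-fold. Leaving out an array or an animal gave 49 to 1251 higher and 225 to 965 lower genes (49 to 939 and 225 to 855). Of 6 higher and 3 lower lists, 0 and 0 passed with an estimated correlation and 2 higher with fry. Without a filter 10 were higher, on the smaller slide 10 and 1, and 1 was lower with the covariate. Reversed medians were those of the lysosome list (0.60 on the smaller slide, 1.19 with the covariate), and with the covariate of disease-associated microglia (0.92), Toll-like receptors (0.37) and the endothelial list itself (-0.55). A change of sign was called reversed where either value was called; in neither were 29 values of genes and 46 of lists. All 54 called named genes kept their sign in every setting that gave a value; 39 stayed called with the animal as a block, 43 with the slide as a block, 9 on the larger slide and 21 on the smaller. Without microglia replicates 1 to 4, 39, 34, 39 and 40 stayed called, and without macrophage replicates 1 to 4, 37, 54, 39 and 47. Calls of named genes that were lost with the animal as a block stand beside them. Genes called only with that block are named or counted beside their lists only in part. Of the list calls the block changed only that of the extracellular matrix list. Signal over background limits dim genes: 116 called genes have only a bound.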

Other observations

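Some of the clearest differences lay outside the fixed lists, and these genes were chosen after their values were seen. Nav3, a neuron navigator family gene, was at least 67.8-fold lower in macrophages (adjusted p = 9.46e-06, limma, lower in 4 of 4 animals), and Hspb3, a small heat shock protein, at least 22.9-fold lower. Olfm4 was at least 11.9-fold lower and Ak1, an adenylate kinase, at least 12.3-fold lower. Lrrc3 was at least 70.1-fold lower (2 of 4 macrophage arrays well above background).

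Xist, which is expressed from the inactive X chromosome, measured 4.69, 2.06, -3.98 and 4.61 in the microglia of animals A to D and -3.73, 0.83, -5.92 and -1.39 in their macrophages (log2 relative to the 75th percentile). Ddx3y, a gene of the Y chromosome, measured -1.30, 1.23, 1.56 and -0.61 in microglia and 1.24, 1.49, 0.54 and 1.31 in macrophages. The labels do not give the sex of the donor or host mice.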
